A study of Mus musculus with 16 samples.

How the data were processed

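Whole-lung total RNA of 16 C57BL/6 mouse lung samples was measured on a single-colour (Cy3) Agilent expression array, 1 array per sample. Per the labels, the CAV1 target site blocker at 5 mg/kg or a control blocker, whose dose was not stated, was given into the trachea 4 and 2 days before and 4 days after bleomycin at 1 unit/kg or phosphate-buffered saline (PBS), to mice of 9 to 12 weeks. A target site blocker is an oligonucleotide that covers a microRNA binding site in a transcript, here in that of Cav1, and the control blocker is its comparison. The labels give 0.2 µg of RNA per array. The time of lung collection, the slide or date of each array, the scanner and the background correction were not stated in the labels. The labels do not say in words that each sample came from a separate animal, so p-values measure the spread between these samples.

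The deposited values are log2 intensities, and per the submitters' processing notes they were made with limma, whose version was not given. Their distribution was nearly the same in all 16 arrays, as after quantile normalization. The minimum lay between 5.39 and 5.41, the median between 6.51 and 6.52, and the maximum was 18.28 in each. The values were not centred per gene, and they were used as deposited. No detection or saturation marks were used here. The number of arrays limits the precision.

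Of 62976 spots, 31465 carried 1 gene symbol and 31511 carried none in the table used here. RefSeq accessions matched 29036 of the named spots to current symbols (mouse assembly GRCm38.p6, used for names only), which changed the symbol of 2933, and 2429 named spots had no match and kept their own. These gave 20863 genes, of which 6086 had more than 1 spot, and the spot with the highest mean signal stood for each gene. Genes above the 25th percentile of the array in at least 2 arrays were tested, 20304 in all.

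One mean per group was fitted to all 16 arrays with limma 3.58.1 on R 4.3.3 (lmFit and moderated eBayes statistics, 12 residual degrees of freedom). Groups held 2 arrays (PBS with the control blocker), 2 (PBS with the CAV1 blocker), 6 (bleomycin with the control blocker) and 6 (bleomycin with the CAV1 blocker). The comparisons were bleomycin against PBS under each blocker, the CAV1 blocker against the control blocker after bleomycin and after PBS, and the interaction. All tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Intervals are 95% confidence intervals, and ± gives the SD between arrays of a group.

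A bleomycin response score was the mean log2 signal of the genes called higher in the 12 bleomycin arrays than in the 4 PBS arrays, by at least 1 on the log2 scale, minus the mean of those called lower by as much. Scores and the Cav1 level were compared between the blockers after bleomycin with an exact permutation test over 924 assignments, whose smallest p is 0.00216. A slope related the effect of bleomycin under the CAV1 blocker to that under the control blocker over the same genes.

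Gene lists, 32 in all, were written before the data were examined, and 1 list (stratified squamous epithelium) was added after. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, again with camera at an estimated correlation, and with fry. Genes to be named were fixed by rule before the data were examined. They were Cav1, Dnm3os and Dnm3 in every comparison, and the 10 largest rises and 10 largest falls among called genes whose groups were fully separated. Where no gene was called, the 5 smallest p-values in each direction were named as values. For each list described, up to 4 members with the smallest p were added, with any called member that went the opposite way. Called gene models without a gene name were counted but not named, and numbered 19 with bleomycin under the control blocker, 4 under the CAV1 blocker, 16 with the CAV1 blocker after bleomycin and 3 after PBS.

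Alternatives to these choices covered the dim filter (none, or the 50th percentile), the mean of a gene's spots, spots in place of genes, renewed quantile normalization, median centring, trend and robust moderation, array weights, a fit to the compared arrays only, the replicate number as a block, a block made of the earlier and later 8 samples in deposit order, a log2 fold minimum of 1, and leaving out each of the 16 arrays. Where this left 1 array in a PBS group, that array was assumed to vary like the other groups. Further alternatives were chosen after seeing the data, namely a covariate for skeletal muscle markers, leaving out PBS control blocker array 2 together with bleomycin CAV1 blocker array 6, the covariate without bleomycin CAV1 blocker array 1, and score genes from a fit with the covariate.

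The fit was tested on simulated data made from each gene's mean with normal noise at its residual SD. Chosen genes were shifted in 1 group. The noise was independent between genes, so it lacked the differences between arrays that many genes share in the real data. The rates below hold only without such shared differences. A shift of 1 on the log2 scale was recovered for 85.1% of the shifted genes with bleomycin under the control blocker, for 83.6% under the CAV1 blocker, for 95.5% with the CAV1 blocker after bleomycin, for 61.2% after PBS and for 64.2% in the interaction, with 5 to 11 false calls among 20304 genes.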

Results

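Gene expression was measured in 16 mouse lung samples that had received a CAV1 target site blocker or a control blocker, followed by bleomycin, which injures the lung and leads to fibrosis, or by PBS. Bleomycin arrays numbered 6 with each blocker and PBS arrays 2 with each blocker. Across the 120 pairs of arrays the correlation of log2 signal ranged from 0.970 to 0.998, with a median of 0.989. Within groups the median was 0.991 over 32 pairs. Genes are not independent replicates in these correlations. RNA integrity numbers were 10 in bleomycin control blocker arrays 1 and 5 and 9 in all other samples. These arrays also had the highest bleomycin response scores of their group, 2.10 and 2.37.

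Lungs differed in muscle and squamous epithelial transcripts, within each bleomycin group and between the PBS groups. The mean log2 signal of the skeletal muscle list was 10.32 to 12.86 in 11 arrays and 7.29 to 8.60 in 5 arrays. The stratified squamous epithelium list, added after the data were seen, lay at 10.45 to 11.65 in the same 11 arrays and at 6.45 to 6.50 in the same 5. The 5 low arrays were both PBS CAV1 blocker arrays, bleomycin control blocker arrays 2 and 6, and bleomycin CAV1 blocker array 3. Contrasts that involve the PBS groups therefore carry a difference in muscle and squamous transcripts between the blockers.

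**Figure D1:**
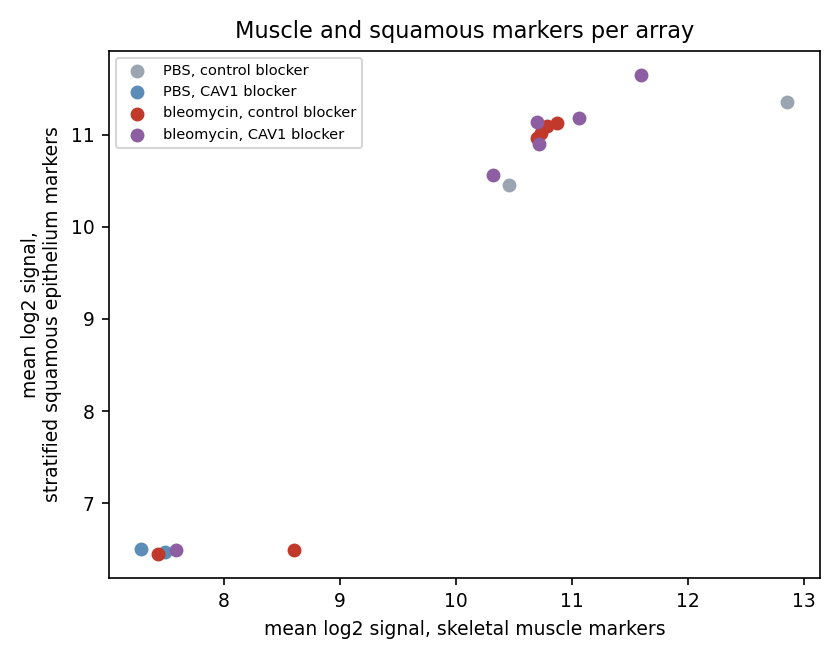
Mean log2 signal of the skeletal muscle list (x axis) against that of the stratified squamous epithelium list (y axis), 1 point per array, coloured by group. The 11 arrays at the upper right lie at or above 10.32 on the x axis, and the 5 at the lower left lie at or below 8.60.

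The comparison of bleomycin with PBS under the control blocker asks how the injured lung differed from the lung without bleomycin. In all, 398 genes rose and 91 fell, and the other genes did not pass the test. Among the rises were Spp1, Ms4a7 and Trem2 of monocyte-derived macrophages, and Grem1 of the extracellular matrix and fibrosis list. Timp1, the chemokine genes Ccl2 and Ccl8 and the cell cycle genes Kif20a and Cdc20 rose too. Spp1 rose by 2.91 (log2, SE 0.637, adjusted p = 0.0302), from 10.78 ± 0.35 (SD, n = 2) to 13.69 ± 0.37 (n = 6). Ms4a7 rose by 2.22 (SE 0.317, adjusted p = 0.0071) and Ccl2 by 2.18 (SE 0.292, adjusted p = 0.00487). The 9 other Ccl2 spots changed by 2.09 to 2.28, and whether they hold different probes was not tested. Fxyd4 (2.20), Timp1 (2.02), Adamts4 (2.01), Lama1 (1.86), Trem2 (1.85), Saa3 (1.82) and Phgr1 (1.81) completed the 10 largest rises. Spag11b changed by -1.69 (adjusted p = 0.0107) and Tff2 by -1.22 (SE 0.145, adjusted p = 0.00184). Krt79 (-1.52), Hes2 (-1.40), Bex2 (-1.36), Igfbp3 (-1.35), Ngp (-1.29), Mlxipl (-1.18), Nrn1 (-1.18) and Ephx2 (-1.08) completed the largest falls. For each of these genes every bleomycin array lay on the same side of both PBS arrays.

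Ccl2, Spag11b, Tff2, Tgfbi, Psrc1, Cxcl10 and Ccl8 were the 7 of 64 named genes, list members included, that passed the bleomycin test under the control blocker whichever of the 16 arrays was left out. Without PBS control blocker array 2, 56 of the 64 no longer passed, among them Spp1 (adjusted p = 0.157), Timp1 (0.148) and Trem2 (0.218), and Ms4a7 came to 0.0558. Without bleomycin control blocker array 1, 33 no longer passed. Leaving out any of 13 further arrays, PBS control blocker array 1, both PBS CAV1 blocker arrays, bleomycin control blocker arrays 2 to 6 and bleomycin CAV1 blocker arrays 2 to 6, ended between 2 and 16 of these calls. The 489 genes became 91 without PBS control blocker array 2, 4075 without PBS control blocker array 1, and 316 without PBS CAV1 blocker array 1 or 2. They became 148, 257, 309 and 248 without bleomycin control blocker arrays 1, 2, 3 and 5, and 279 without bleomycin CAV1 blocker array 2. With the skeletal muscle covariate 193 of the 489 genes remained called, and 401 when bleomycin CAV1 blocker array 1 was also left out.

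**Figure D2:**
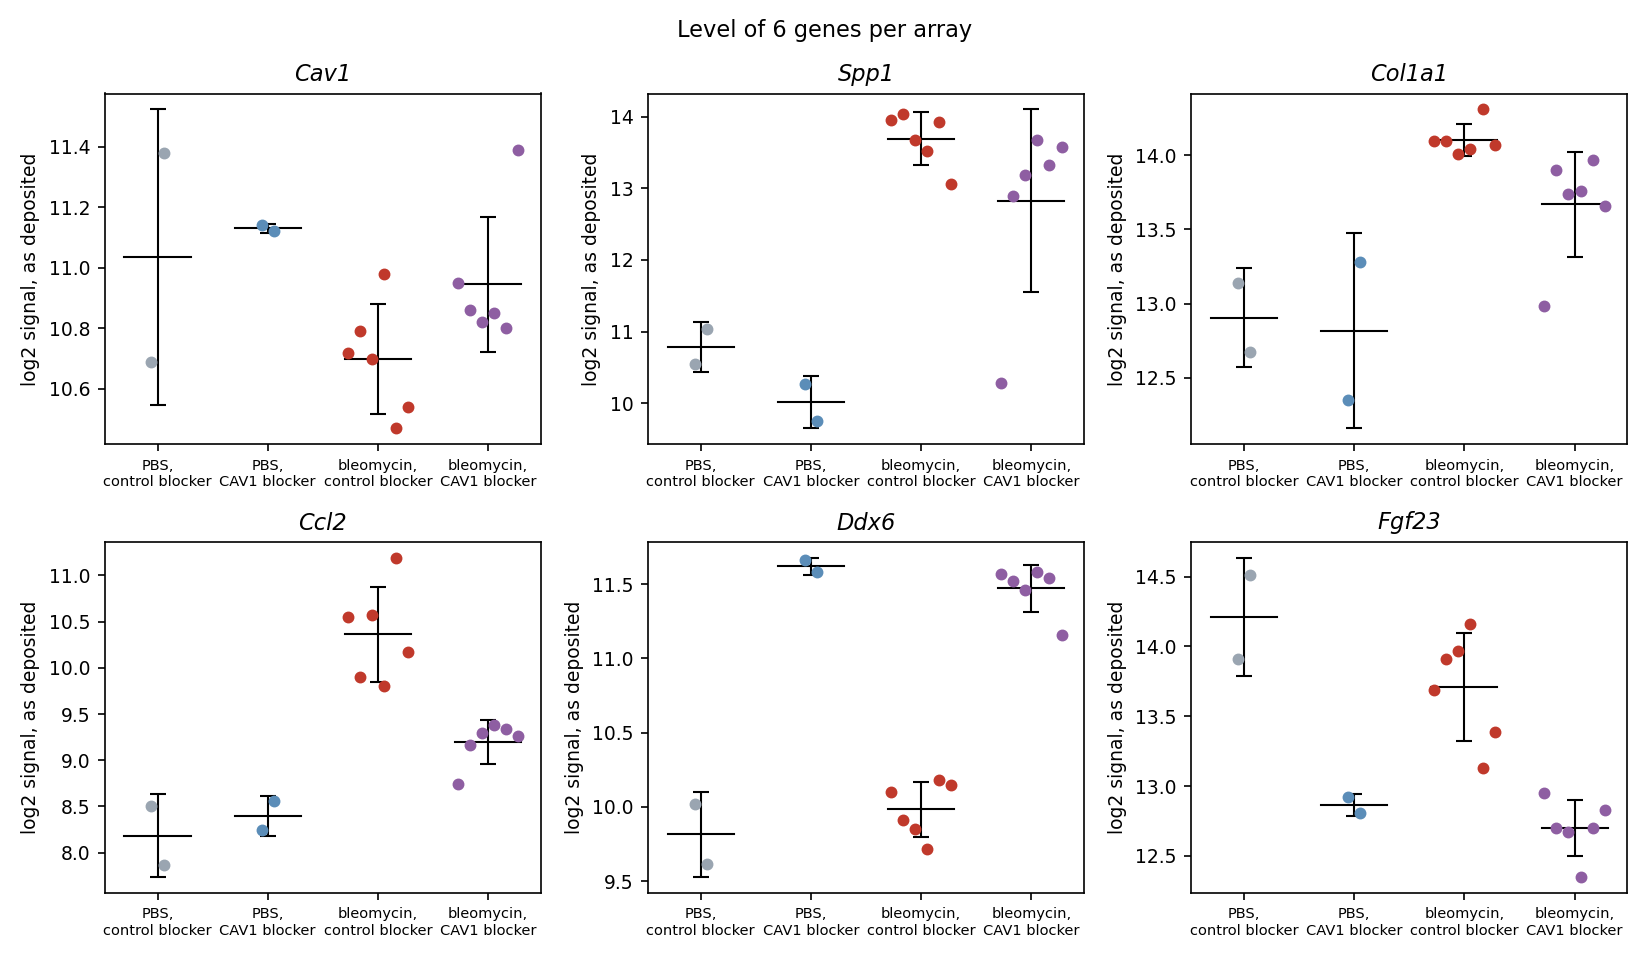
Log2 signal as deposited (y axis) of Cav1, Spp1, Col1a1, Ccl2, Ddx6 and Fgf23 in each array by group, with the group mean and SD. Spp1 rose from 10.78 to 13.69 with bleomycin under the control blocker, and Ddx6 rose from 9.98 to 11.47 with the CAV1 blocker after bleomycin.

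Among the lists fixed before the data were examined, 8 shifted upward and 14 downward with bleomycin under the control blocker (camera, adjusted p under 0.05), and 2 of these 22 calls, the cytokine and eosinophil lists, held with an estimated correlation. Of the 21 monocyte-derived macrophage genes, 6 rose over all genes tested and 17 adjusted over the list alone (median log2 change 1.03, adjusted p = 8.44e-13, and 0.0679 with an estimated correlation), Fcgr1 (1.03) and Cx3cr1 (0.81) among them. Of the 39 extracellular matrix and fibrosis genes, 14 rose, 25 adjusted over the list alone (median 0.58, adjusted p = 4e-16, and 0.0679 with an estimated correlation), with Lox at 0.69, Grem1 at 1.49 and Col1a2 at 0.90. Cell cycle genes rose in 10 of 29 cases, 19 adjusted over the list alone (median 0.72, adjusted p = 8.44e-13, and 0.117 with an estimated correlation), Kif20a (1.51), Cdc20 (1.40), Ccna2 (1.35) and Tpx2 (1.22) among them. Interferon response genes rose in 7 of 23 cases, 12 adjusted over the list alone (median 0.43, adjusted p = 3.38e-09, and 0.0679 with an estimated correlation), with Cxcl10 at 1.63 (adjusted p = 9.76e-04), Mx1 at 1.08, Cxcl9 at 0.92 and Oas1a at 0.90. Cytokines and chemokines rose in 6 of 30 cases, 11 adjusted over the list alone (median 0.25, adjusted p = 2.13e-05, and 0.0415 with an estimated correlation), with Ccl12 at 1.52 and Ccl17 at 0.84. The interferon median was 0.28 without PBS control blocker array 2. Ccl8 rose by 1.63 (adjusted p = 9.76e-04).

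Genes of p53 and DNA damage rose in 6 of 23 cases with bleomycin under the control blocker, 9 adjusted over the list alone (median 0.40, adjusted p = 2.42e-07, and 0.0679 with an estimated correlation), with Psrc1 at 1.63, Tnfrsf10b at 0.88, Ccng1 at 0.77 and Zmat3 at 0.64. The TGF-beta response list had 5 of 21 genes risen, 6 adjusted over the list alone (median 0.25, adjusted p = 0.00106, and 0.0679 with an estimated correlation), with Ccn2 at 0.89, Inhba at 0.86, Pmepa1 at 0.71 and Tgfbi at 0.68. Transitional alveolar epithelium genes rose in 3 of 14 cases, 7 adjusted over the list alone (median 0.51, adjusted p = 2.27e-04, and 0.17 with an estimated correlation), namely Cldn4 (0.98), Tnfrsf12a (0.81) and Hbegf (0.62). Without PBS control blocker array 1 the TGF-beta list came to an adjusted p of 0.291 and the transitional list, with a median of 0.32, to 0.438.

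Lists of lymphoid, eosinophil, endothelial and lipid synthesis genes shifted downward with bleomycin under the control blocker. The eosinophil list had 0 of 6 genes called by limma over all genes tested, with 4 lower at an unadjusted p under 0.05, and 4 fallen adjusted over the list alone (median -0.46, adjusted p = 4.16e-04, and 0.0415 with an estimated correlation). Lipid and sterol synthesis genes fell in 3 of 18 cases, 4 adjusted over the list alone (median -0.28, adjusted p = 7.15e-04, and 0.0679 with an estimated correlation), namely Insig1 (-0.75), Lpin1 (-0.51) and Acly (-0.48). Resident alveolar macrophage genes fell in 2 of 13 cases, with 2 risen and 6 fallen adjusted over the list alone (median -0.39, adjusted p = 0.0012, and 0.0679 with an estimated correlation), Marco (-0.99) among them. The T cell and NK cell list had 1 of 19 genes fallen, Cd3e (-0.63), and 5 adjusted over the list alone (median -0.33, adjusted p = 2.13e-05, and 0.0943 with an estimated correlation). Endothelial genes gave 1 rise, Sox17 (0.44), and 1 fall, Acvrl1 (-0.61), among 22, with 1 rise and 5 falls adjusted over the list alone (median -0.28, adjusted p = 3.13e-05, and 0.112 with an estimated correlation).

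The B cell and plasma cell list shifted downward with 0 of 12 genes called by limma on either scale and 1 lower at an unadjusted p under 0.05 (median -0.23, adjusted p = 0.00474, and 0.28 with an estimated correlation). The neutrophil list had 1 of 15 genes fallen, Ngp, over all genes and adjusted over the list alone (adjusted p = 0.0396, and 0.262 with an estimated correlation), and the resting fibroblast list 1 of 14, Inmt (-0.90), on both scales (0.0216, and 0.105 with an estimated correlation). Club and secretory genes gave 1 rise, Retnla (1.73), and 2 falls, Scgb3a1 (-0.69) and Muc5b (-0.62), among 13 on both scales (0.0271, and 0.124 with an estimated correlation). The smooth muscle and myofibroblast contractile list had 0 of 14 genes called by limma on either scale, with 1 higher and 3 lower at an unadjusted p under 0.05 (median -0.10, 0.0431, and 0.194 with an estimated correlation).

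Adipocyte genes fell in 8 of 10 cases adjusted over the list alone and in 0 over all genes by limma, 8 at an unadjusted p under 0.05, with bleomycin under the control blocker (median -1.42, adjusted p = 1.63e-06, and 0.109 with an estimated correlation). Skeletal muscle genes fell in 1 of 12 cases adjusted over the list alone and in 0 over all genes by limma, 4 at an unadjusted p under 0.05 (median -1.88, 1.83e-05, and 0.253 with an estimated correlation), and cardiac muscle genes in 0 of 13 on either scale, 5 at an unadjusted p under 0.05 (median -0.58, 3.98e-04, and 0.278 with an estimated correlation). With the skeletal muscle covariate, which is the mean of this list, its median was 0.051 (adjusted p = 0.679). The erythroid and platelet list had 1 of 9 genes fallen, Hbb-bt (-0.71, adjusted p = 0.0491), a paralog of other globin genes whose signal is uncertain, and 3 adjusted over the list alone (median -0.60, 2.44e-05, and 0.117 with an estimated correlation).

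Several downward calls with bleomycin under the control blocker rested on single arrays. Without PBS control blocker array 1, the adjusted p was 0.0647 for resident alveolar macrophages, 0.197 for neutrophils, 0.538 for T and NK cells, 0.112 for B cells, 0.109 for eosinophils, 0.158 for club cells and for resting fibroblasts, 0.427 for smooth and cardiac muscle and 0.223 for skeletal muscle. Without PBS control blocker array 2 it was 0.0974 for neutrophils, endothelial cells and resting fibroblasts and 0.165 for club cells. The neutrophil list came to 0.0787 and 0.0756 without bleomycin control blocker arrays 2 and 3, and smooth muscle to 0.0741 and 0.0706 without bleomycin control blocker arrays 2 and 6. Medians moved as well, and leaving out PBS control blocker array 1 they were -0.22 for resident alveolar macrophages, 0.039 for neutrophils, 0.019 for T and NK cells, -0.062 for resting fibroblasts, -0.097 for cardiac muscle and -0.67 for skeletal muscle. Without PBS control blocker array 2 they were -0.20 for smooth muscle, -0.13 for neutrophils, -0.63 for T and NK cells, -0.084 for endothelial genes, -0.11 for lipid synthesis and -2.86 for skeletal muscle. Without bleomycin control blocker array 2 they were -0.14 for B cells and -0.37 for cardiac muscle, and without array 6 of that group -0.33 for cardiac and -1.24 for skeletal muscle.

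The lists without a shift with bleomycin under the control blocker were those of caveolae (camera adjusted p = 0.842, where the median was 0.02 and the mean -0.02), the blocker target and miR-199a host locus (0.797), dendritic and mast cells (0.78), ciliated cells (0.956), basal cells (0.345) and the unfolded protein response (0.383), with 0 genes called by limma in each on either scale. At an unadjusted p under 0.05, 1 caveolae gene, 1 gene of the blocker locus, 5 of 14 dendritic and mast cell genes, 2 ciliated genes, 0 basal genes and 3 unfolded protein response genes differed. Sex-linked genes had an adjusted p of 0.78, with a positive median (0.05) and a downward test. Alveolar type 2 genes (0.255) had 1 rise, Ctsh (0.81), and alveolar type 1 genes (0.383) had 1 rise, Spock2 (1.14), each on both scales. Oxidative stress genes (0.383) had 3 rises on both scales, Mt2 (0.95), Mt1 (0.57) and Gclc (0.38).

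Bleomycin was compared with PBS under the CAV1 blocker to ask the same question where the blocker was present. Here 70 genes rose and 35 fell. Psrc1 rose by 1.85 (log2, SE 0.225, adjusted p = 0.00413) and Spag11b changed by -2.14 (SE 0.269, adjusted p = 0.00454), and these 2 of the 20 named genes passed whichever array was left out. Thbs4 (2.65), Trem2 (2.25), Cdkn1a (2.01), Fxyd4 (2.01), Kng1 (1.80) and Cdc20 (1.62) also rose. Sprr1a (3.38), Mybpc2 (2.26) and S100a14 (2.18) rose as well, and these were low in both PBS CAV1 blocker arrays along with the muscle and squamous transcripts. Sprr1a stood at 7.66 in that PBS group, 11.21 in the PBS control blocker group and 10.84 after bleomycin with the control blocker. Hes2 (-1.77), Orm3 (-1.20), Ripor2 (-1.08), Asgr1 (-1.03), Arhgef38 (-0.95), Acoxl (-0.94) and Kitl (-0.81) fell, as did the paralogs Klra8 (-0.92) and Klra7 (-0.91), whose signals are uncertain. With the skeletal muscle covariate 9 of the 105 genes remained called, and 70 when bleomycin CAV1 blocker array 1 was also left out.

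The number of genes changed by bleomycin under the CAV1 blocker moved with nearly every array. It was 719 without bleomycin CAV1 blocker array 1, which kept all 105 genes, and 15, 56, 11, 10 and 15 without arrays 2, 3, 4, 5 and 6 of that group. It was 27, 23, 28, 30 and 69 without bleomycin control blocker arrays 1 to 5, 312 without PBS control blocker array 1 or 2, and 40 and 25 without PBS CAV1 blocker arrays 1 and 2. Of the 20 named genes, 17 no longer passed without PBS CAV1 blocker array 1 and 18 without array 2, among them Trem2 (adjusted p = 0.346 without PBS CAV1 blocker array 1). Leaving out bleomycin CAV1 blocker arrays 2 to 6 or any bleomycin control blocker array ended between 5 and 17 of these calls.

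Cell cycle genes had the smallest camera p at the preset correlation with bleomycin under the CAV1 blocker, though not the largest median. Of 29, 6 rose and 18 adjusted over the list alone (median 0.77, camera adjusted p = 3.58e-16, and 0.214 with an estimated correlation). Monocyte-derived macrophage genes rose in 1 case and in 16 adjusted over the list alone (median 0.91, 1.2e-13, and 0.162 with an estimated correlation). The transitional epithelium list had 3 rises and 8 adjusted over the list alone (1.11e-09, and 0.162 with an estimated correlation), the p53 list 5 and 11 (3.64e-09, and 0.162 with an estimated correlation), and the matrix list 0 by limma, 19 at an unadjusted p under 0.05, and 15 adjusted over the list alone (2.65e-09, and 0.214 with an estimated correlation). Skeletal muscle genes (median 3.12, 1.77e-07, and 0.263 with an estimated correlation) and basal cell genes (1.22, 3.11e-04, and 0.214 with an estimated correlation) shifted upward, and both PBS CAV1 blocker arrays were low in them. The transitional list, which holds Sprr1a, was also lower in these PBS arrays (mean log2 11.39 and 11.46) than in the PBS control blocker arrays (11.76 and 12.14). Oxidative stress genes shifted upward (0.0238, and 0.307 with an estimated correlation), and endothelial (3.21e-05, and 0.214 with an estimated correlation) and T and NK cell genes (0.0163, and 0.342 with an estimated correlation) downward. The interferon (0.617), cytokine (0.105) and TGF-beta (0.0514) lists did not pass.

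Both effects of bleomycin shared 42 risen and 5 fallen genes, against 1.37 and 0.157 for independent draws, and 0 genes were called in opposite directions. Independent draws are a rough reference only, since each gene's spread came from the same fit in both comparisons and genes vary together. Of the 489 genes called under the control blocker, 457 (93.5%) had the same sign under the CAV1 blocker. Across these genes, which are not independent replicates, r was 0.828 and rho 0.848, and over all genes r was -0.052.

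The CAV1 blocker was compared with the control blocker after bleomycin to ask what the blocker changed in the injured lung. In all, 243 genes rose and 84 fell, the chemokine genes Ccl2 and Cxcl10, the macrophage gene Ms4a7 and the interferon-induced gene Mx1 among the falls. Ccl2 changed by -1.17 (log2, SE 0.206, adjusted p = 0.00544), from 10.36 ± 0.52 (SD, n = 6) to 9.20 ± 0.24 (n = 6). Its 9 other spots, which may be copies of 1 probe, changed by -1.18 to -1.05. Ms4a7 changed by -1.05 (SE 0.224, adjusted p = 0.0236). Ddx6 rose by 1.49 (SE 0.101, adjusted p = 1.43e-06), from 9.98 ± 0.18 to 11.47 ± 0.16, and Rc3h2 by 1.22 (SE 0.0825, adjusted p = 1.43e-06). Hira (1.38), Slc29a3 (1.27), Abca8a (1.26) and Rnf181 (1.26) rose, as did the histone H4 genes H4c4 (1.28), H4f16 (1.23), H4c14 (1.20) and H4c12 (1.19), close paralogs whose signals are uncertain. Fgf23 changed by -1.01 (adjusted p = 0.00301), and Pign (-1.11), Krt222 (-1.08), Marchf1 (-1.05), Lhx6 (-1.01), Tacr2 (-0.99), Pdzrn3 (-0.99) and Slc17a5 (-0.98) fell.

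Other spots of these genes, where bright enough to tell, changed alike for some genes after bleomycin. The other spot of H4c12, at a mean log2 signal of 10.82, changed by 1.12, that of Rnf181 (11.76) by 0.69, and those of the list members Cald1 (8.41) by 0.88 and Cat (9.65) by -0.44. The 10 other spots of Marchf1, at 9.47 to 9.98 and possibly copies of 1 probe, changed by only -0.10 to -0.05. The other spot of Slc17a5 (8.40) changed by -0.06. Other spots of Fgf23, Pign, Krt222, Slc29a3 and H4c14 lay at 5.95 to 6.33, too near the floor to show a change. Those of Lhx6 and Tacr2 lay at 5.93 to 6.66. The called spots were brighter, at 13.29 for Fgf23, 12.24 for Krt222, 13.38 for H4c14 and 9.16 for Pign. Those of Lhx6, Tacr2 and Slc29a3 lay at 11.93, 12.27 and 7.16. Spots of the same gene thus differed in level, and whether the brighter spot measures the named transcript was not tested. The count stayed between 249 and 394 when any array was left out, and 22 of the 32 named calls, Ccl2 and Ddx6 among them, passed in every case. The other 10 reached their highest adjusted p without bleomycin control blocker array 1 (Inhba 0.0816, Ei24 0.0581, Il6 0.103), array 2 (Cat 0.107, Hbb-bt 0.0859), array 5 (Ms4a7 0.0619, Aldh1a1 0.103) or array 6 (Itgb6 0.0982), or without bleomycin CAV1 blocker array 2 (Cxcl10 0.0654, Mx1 0.0896). Leaving out any array other than PBS control blocker array 1 or 2 ended at least 3 of these calls.

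Of the lists, 5 shifted downward and 4 upward with the CAV1 blocker after bleomycin (camera, adjusted p under 0.05), and 0 did so with an estimated correlation, while fry called 3, all downward. Leaving out any array ended none of the 9 calls, but it moved some list medians. Without bleomycin CAV1 blocker array 1 the median went to -0.25 for monocyte-derived macrophages, -0.13 for matrix, -0.058 for cytokines and chemokines and 0.10 for neutrophils. It went to -0.17 for cytokines and chemokines without bleomycin CAV1 blocker array 6. Monocyte-derived macrophage genes had 1 fall over all genes tested, Ms4a7, and 6 adjusted over the list alone among 21 (median -0.39, adjusted p = 6.49e-08, and 0.266 with an estimated correlation). Cx3cr1 (-0.48, adjusted p = 0.0964) and Gpnmb (-1.14, adjusted p = 0.24) did not pass. Of the 39 extracellular matrix and fibrosis genes, 37 were lower, yet 0 passed limma's test over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05 (median -0.21, adjusted p = 2.91e-07, and 0.281 with an estimated correlation), and Col5a2 (-0.70, adjusted p = 0.112) and Col1a2 (-0.36, adjusted p = 0.236) were members. Interferon response genes fell in 2 of 23 cases, Cxcl10 (-0.57, adjusted p = 0.0244) and Mx1 (-0.59, adjusted p = 0.0327), and in 8 adjusted over the list alone (median -0.19, adjusted p = 2.97e-07, 0.191 with an estimated correlation, 0.0292 by fry). Cytokines and chemokines fell in 2 of 30 cases, Ccl2 and Il6 (-0.91, adjusted p = 0.0407), and in 4 adjusted over the list alone (median -0.12, 0.00282, 0.191 with an estimated correlation, 0.0292 by fry). The TGF-beta response list had 1 of 21 genes fallen, Inhba (-0.59, adjusted p = 0.0291), and 3 adjusted over the list alone (median -0.13, 0.00586, 0.191 with an estimated correlation, 0.0292 by fry).

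Erythroid and platelet genes rose in 1 of 9 cases with the CAV1 blocker after bleomycin, Hbb-bt (0.57, adjusted p = 0.03), a globin paralog of uncertain signal, and in 4 adjusted over the list alone (median 0.49, adjusted p = 2.52e-06, and 0.237 with an estimated correlation). Endothelial genes rose in 1 of 22 cases, Calcrl (0.68, adjusted p = 8.39e-04), and in 2 adjusted over the list alone (0.00125, and 0.281 with an estimated correlation). The adipocyte list (median 0.48, 0.00343, and 0.435 with an estimated correlation) and the neutrophil list (0.32, 0.00644, and 0.273 with an estimated correlation) had 0 genes called by limma on either scale, with 2 and 3 higher at an unadjusted p under 0.05. The median was 0.12 for endothelial genes and 0.065 without bleomycin control blocker array 5, that of adipocyte genes 0.30 without bleomycin CAV1 blocker array 2, and that of neutrophil genes 0.10 without bleomycin CAV1 blocker array 1. Ucp1, a gene of brown fat, differed by 2.20 (adjusted p = 0.466).

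Alveolar and airway lists did not shift with the CAV1 blocker after bleomycin (camera adjusted p, alveolar type 2 0.38, alveolar type 1 0.134, transitional epithelium 0.135, club 0.273, ciliated 0.368, basal 0.874), although Itgb6 (0.64, adjusted p = 0.0398) and Aldh1a1 (0.38, adjusted p = 0.0422) rose and Mcidas (-0.93, adjusted p = 0.00231) fell. Adjusted over the list alone, transitional genes gave 1 rise and 3 falls among 14, alveolar type 1 genes 2 rises, p53 genes 1 rise and 1 fall, oxidative stress genes 4 falls, and club, ciliated, smooth muscle, eosinophil and dendritic and mast cell genes 1 call each. Leukocyte lists gave 0.38 for resident alveolar macrophages, 0.737 for T and NK cells, 0.337 for B cells, 0.917 for dendritic and mast cells and 0.875 for eosinophils. The smooth muscle list gave 0.643, with Cald1 risen (0.65, adjusted p = 2.39e-04), and the p53 list 0.0675, with Ei24 risen (0.50, adjusted p = 0.0229). Oxidative stress gave 0.164, with Cat fallen (-0.58, adjusted p = 0.0415). Adjusted p was 0.0603 for resting fibroblasts, 0.0675 for the cell cycle, 0.735 for lipid synthesis, 0.301 for the unfolded protein response, 0.134 for cardiac muscle, 0.135 for skeletal muscle and for sex-linked genes, 0.368 for caveolae and 0.576 for the blocker target and miR-199a host locus.

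The level of Cav1, the transcript the blocker targets, did not differ by the test between the blockers. It was 10.70 ± 0.18 (SD, n = 6) with the control blocker and 10.94 ± 0.22 (n = 6) with the CAV1 blocker after bleomycin, a difference of 0.24 (log2, SE 0.126, interval -0.025 to 0.51, adjusted p = 0.642, exact permutation p = 0.0519). Without bleomycin Cav1 was 11.04 ± 0.49 (SD, n = 2) and 11.13 ± 0.01 (n = 2), and the CAV1 blocker differed by 0.09 (adjusted p = 0.855). Bleomycin changed Cav1 by -0.34 (SE 0.179, adjusted p = 0.378) under the control blocker and by -0.18 (adjusted p = 0.681) under the CAV1 blocker, with an interaction of 0.15 (adjusted p = 0.768). Under the control blocker the change was -0.68 and passed (adjusted p = 0.0294) without PBS control blocker array 1, and it was 0.0073 (adjusted p = 0.995) without PBS control blocker array 2, with p from 0.0294 to 1 over 29 alternatives. The difference after PBS was -0.25 and the interaction 0.50 without PBS control blocker array 1, and they were 0.44 and -0.19 without PBS control blocker array 2. Without bleomycin CAV1 blocker array 6, whose Cav1 level was 11.39 against 10.80 to 10.95 in the other 5 arrays, the difference after bleomycin was 0.16 (adjusted p = 0.827, from 0.408 to 0.876 over 29 alternatives) and the interaction 0.065. Dnm3os, which hosts miR-199a, did not pass in any comparison, with 0.31 (adjusted p = 0.305) and -0.17 (0.61) for bleomycin under the control and the CAV1 blocker, -0.14 (0.83) and 0.34 (0.407) for the CAV1 blocker after bleomycin and after PBS, and -0.48 (0.497) for the interaction. Dnm3, its neighbour, did not pass either (adjusted p from 0.903 to 0.996).

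The CAV1 blocker was also compared with the control blocker after PBS, where no injury was present. Here 56 genes rose and 7 fell. Ddx6 rose by 1.81 (log2, adjusted p = 5.74e-04), Rc3h2 by 1.41 (adjusted p = 5.74e-04) and Dstyk by 1.42 (adjusted p = 0.00286), and Sptan1 (1.42), Abca8a (1.28), Hira (1.27) and the H4 paralogs H4c12 (1.45), H4f16 (1.43), H4c14 (1.34) and H4c4 (1.19) rose as well. Pign (-1.43), Slc17a5 (-1.35), Mcidas (-1.26), Myoc (-0.73) and Ces2c (-0.50) fell, and Mybpc2 (-2.28, adjusted p = 0.0454) and Hspb7 (-1.73) fell with the muscle transcripts that were low in both PBS CAV1 blocker arrays. Ddx6, Rc3h2, Dstyk, H4c12, H4f16 and H4c14 passed whichever array was left out. Of the 17 named calls, 10 were lost without PBS CAV1 blocker array 2 (Abca8a, adjusted p = 0.187), 9 without array 1 of that group (Mybpc2, 0.289), 6 without PBS control blocker array 2, and 1 to 5 without bleomycin control blocker arrays 1 to 4 and 6 or any bleomycin CAV1 blocker array. The 63 genes became 4024 and 168 without PBS control blocker arrays 1 and 2, 34 without PBS CAV1 blocker array 2, 41 and 40 without bleomycin control blocker arrays 1 and 3, and 41 without bleomycin CAV1 blocker array 5. Lists that shifted were skeletal muscle (median -4.01, camera adjusted p = 4.18e-12, and 0.36 with an estimated correlation), basal cells (-1.20, 3.69e-04, and 0.36 with an estimated correlation), interferon (0.18, 0.031, and 0.611 with an estimated correlation), and, each with an adjusted p of 0.0165, resident alveolar macrophages and lipid synthesis (0.36 with an estimated correlation) and monocyte-derived macrophages, transitional epithelium and cardiac muscle (0.611 with an estimated correlation). The lists at 0.0165 had lower group means with the CAV1 blocker than with the control blocker. For monocyte-derived macrophages the mean log2 was 10.355 against 10.812 (n = 2 each). After bleomycin this list stood at 11.415 with the CAV1 blocker and 11.861 with the control blocker, a difference of similar size.

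The genes called for the CAV1 blocker after bleomycin mostly had the same sign after PBS, in arrays that the comparisons do not share. Both gave 52 of the same rises, against 0.67 for independent draws, and 4 of the same falls, against 0.029, and 0 genes were called in opposite directions. Both comparisons take each gene's spread from the same fit, and genes vary together, so independent draws are a rough reference only. Of the 327 genes called after bleomycin, 304 (93%) had the same sign after PBS, 241 of the 243 rises and 63 of the 84 falls. Across these 327 genes, which are not independent replicates, r was 0.834 and rho 0.746, and over all genes r was -0.13. Ccl2 and Ms4a7 were not among the shared calls.

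**Figure D3:**
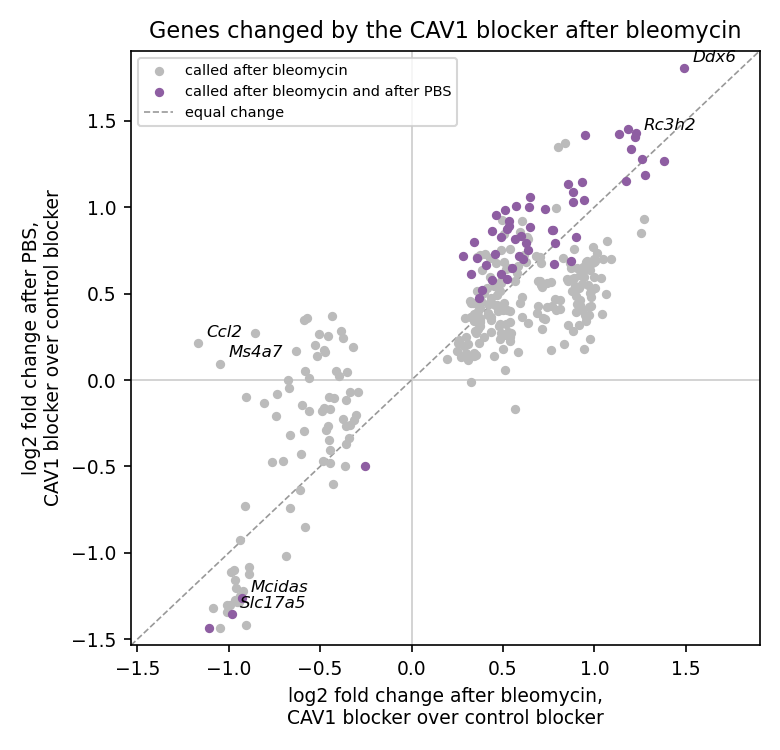
Log2 fold change of the CAV1 blocker over the control blocker after bleomycin (x axis) and after PBS (y axis) for the 327 genes called after bleomycin, 1 point per gene. Genes called in both comparisons are purple, and 304 of the 327 points have the same sign on both axes.

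Whether the blocker altered the response to bleomycin was tested with the interaction and with the response score. Limma called 0 genes for the interaction, with 1873 at an unadjusted p under 0.05. The smallest adjusted p was 0.497, shared by Myoc (0.66), Gsta4 (0.66), Mybpc2 (2.30), Hspb7 (1.51), Mylpf (1.01), Slfn9 (-0.62), Plod2 (-0.66), Rnf13 (-0.71), Adm (-1.11) and Cxcl5 (-1.27), which are given as values only. The count became 3011 without PBS control blocker array 1, 41 without array 2 of that group, and 14 without PBS CAV1 blocker array 1 or 2. Of the 10 genes, all but Mylpf passed without PBS control blocker array 1 (adjusted p from 0.00888 to 0.0485), Cxcl5 without PBS CAV1 blocker array 1 (-1.78, adjusted p = 0.0123) and Mybpc2 without PBS control blocker array 2 (2.98, adjusted p = 0.0268). The response score, from 89 risen and 10 fallen genes, was 1.81 ± 0.35 (SD, n = 6) with the control blocker and 1.13 ± 0.86 (n = 6) with the CAV1 blocker after bleomycin, a difference of -0.69 (exact permutation p = 0.0584). After PBS it was -0.89 ± 0.12 (n = 2) and -1.56 ± 0.15 (n = 2), a difference of -0.68. Bleomycin arrays thus exceeded PBS arrays by 2.70 under the control blocker and by 2.69 under the CAV1 blocker. With the score genes fixed, the difference without bleomycin CAV1 blocker array 1 was -0.37 (exact permutation p = 0.126), and with the score built again it was -0.42 (exact permutation p = 0.0866). The difference passed without bleomycin CAV1 blocker array 4 (-0.91, exact permutation p = 0.0173) and without bleomycin control blocker array 6 (-0.80, exact permutation p = 0.0498), and p ranged from 0.0173 to 0.238 over the alternatives. Across the 99 score genes, which are not independent replicates and were chosen on both effects together, the slope of the effect under the CAV1 blocker on that under the control blocker was 0.894 (jackknife SE 0.203, Pearson's r 0.876, Spearman's rho 0.273), and 60 of the 99 effects were smaller in size under the CAV1 blocker.

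**Figure D4:**
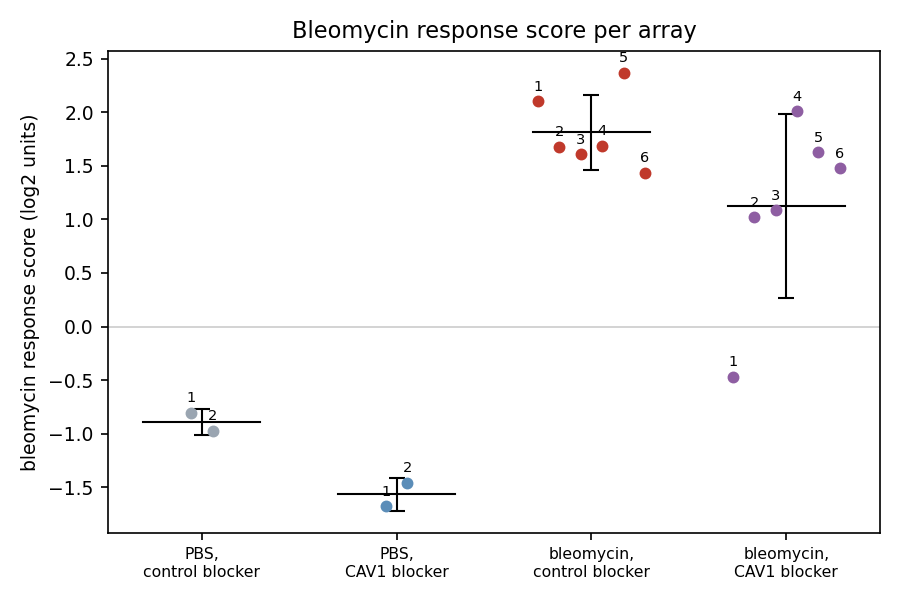
Bleomycin response score (y axis, log2 units) of each array by group, with the group mean and SD. The 6 bleomycin control blocker arrays lie between 1.44 and 2.37 and the 6 bleomycin CAV1 blocker arrays between -0.47 and 2.01.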

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

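The 3 counts over other splits of the arrays, the comparison over all other spots and the blocker label of bleomycin CAV1 blocker array 1 were tests fixed before the result was seen, and every other test in this part was chosen after.

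Single arrays stood far from the other 5 of their group in 8 of 64 list means and 13 of 140 gene values, and in 0 of 2 groups for the score. Chance alone sets apart about 1 group in 20. Bleomycin CAV1 blocker array 1 held 10 of these values. It was low for the matrix list (mean log2 10.11), monocyte-derived macrophages (10.53), Spp1 (10.28), Fxyd4 (8.43), Ccl2 (8.74), Trem2 (10.67) and the unfolded protein response (11.64), and high for the cardiac list (11.50), Spag11b (8.13) and Hes2 (8.69). Array 3 of that group stood apart for the blocker target locus (8.62), Dnm3 (8.50), skeletal muscle (7.59), Sprr1a (9.30) and Mybpc2 (8.93). The remaining values were monocyte-derived macrophages in bleomycin control blocker array 6 (11.55), Trem2 in array 2 (13.67) and Slfn9 in array 4 (9.68) of that group, and T and NK cells in array 5 (9.29), Cav1 in array 6 (11.39) and Ddx6 in array 6 (11.16) of the bleomycin CAV1 blocker group.

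Bleomycin CAV1 blocker array 1 lay nearest the PBS arrays in the response score, at -0.47. For a swap with a PBS array, 0 PBS arrays had a score at or above the lowest of the other bleomycin arrays. The score genes were chosen with the labels in doubt, which favours low scores in PBS arrays, so the score alone does not exclude a swap. A wrong blocker label was excluded on 226 genes that rose with the CAV1 blocker without this array. Over these genes its mean log2 was 10.18, above every control blocker array (9.52 to 9.83) and just under the other CAV1 blocker arrays (10.21 to 10.35). The 20 p53 and DNA damage genes outside the score averaged 10.51 in this array, against 10.57 to 10.80 in the other bleomycin arrays and 10.30 to 10.47 in the PBS arrays. No PBS array thus reached the other bleomycin arrays in this list, which was fixed without the labels and argues against a swap. Less bleomycin in this lung and a single wrong bleomycin label would both lower this list, so they cannot be told apart and stay open, and no biological explanation was tested.

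For 9 gene lists the effect of bleomycin differed between the blockers by the interaction test of camera, and 0 of these calls held with an estimated correlation, while fry called the interferon and cytokine lists (adjusted p = 0.0439 for each). The adjusted p was 0.0191 for extracellular matrix (0.74 with an estimated correlation), 0.00617 for resident alveolar macrophages (0.224), 5.99e-04 for basal cells (0.291), 3.61e-06 for interferon (0.224), 0.0192 for cytokines (0.245), 0.0128 for lipid synthesis (0.224), 3.42e-13 for skeletal muscle (0.224), 0.00617 for erythroid and platelet genes (0.495) and 0.00169 for adipocytes (0.495). Median interactions were -0.34 for matrix, -0.39 for interferon, -0.27 for cytokines, 4.57 for skeletal muscle and 1.32 for basal cells.

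Skeletal muscle and squamous transcripts marked a difference between lungs. All 16 arrays fell on the same side of the midpoint for both lists, as tissue that holds both cell types would give. No gene of either list is in another. The squamous list was added after the data were seen, so this agreement describes the arrays and is not an independent test of that explanation. Krt13 lay at 13.70 to 14.97 in the 11 high arrays and at 5.97 to 6.08 in the 5 low ones, and Acta1 at 12.95 to 14.70 and at 7.53 to 9.87. An effect of bleomycin or of the blocker was excluded as the whole cause, because 2 groups had arrays on both sides. Tissue taken along with the lung is a candidate explanation, and in the PBS groups the difference is confounded with the blocker, since both control blocker arrays were high and both CAV1 blocker arrays low.

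Chance was excluded for the genes changed by the CAV1 blocker after bleomycin, since 1 of 100 splits of the 12 arrays, the real one with 327 genes, gave as many, and the highest other gave 13. It was not excluded for the gene lists, where 24 of 100 splits gave at least the 9 lists of the real one and the highest other gave 16. The median of the other splits was 6 lists, and a split by deposit order gave 8. For bleomycin over both blockers, 3 of 100 splits of the 16 arrays, the real one among them, gave at least the real 950 genes. This met the limit fixed beforehand, but only 100 of the 1820 possible splits were drawn. Because other groupings of the arrays called more genes, structure of the samples alone can give such a count, and it was not excluded. The highest other split called 6773, which points to a structure of the samples, with PBS control blocker array 2, bleomycin CAV1 blocker array 6 and bleomycin control blocker arrays 3 and 4 in its smaller group. The other split above the real count called 1122, and 3 of the 4 arrays in its smaller group were low in muscle transcripts.

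The genes changed by the CAV1 blocker after bleomycin were weighed against technical causes. Muscle and squamous tissue taken with the lung was excluded as the whole cause, since 94.2% of the rises and 78.6% of the falls remained called with the muscle covariate. The covariate follows skeletal muscle markers only, so other tissue taken with the lung, such as fat, was not tested. An error limited to the bleomycin arrays was excluded for the rises, of which 99.2% had the same sign in the PBS arrays. It stays open for the falls as a set, with 75%. Of the falls, 4 were also called lower after PBS, while Ccl2 and Ms4a7 were not lower there. The median change at 28 other spots of 20 risen genes was 0.0394 of that at the called spots (0.00376 to 0.128), and at bright spots 0.0334 for rises (-0.118 to 0.209, 12 spots of 10 genes), while for falls it was 0.104 over all other spots (-0.00315 to 0.397, 11 spots of 10 genes) and 0.351 at bright ones (0.0781 to 1.13, 5 spots of 4 genes). Genes that rose with bleomycin gave 0.198 (0.058 to 0.521) and, at bright spots, 0.613 (-0.0619 to 0.949), ranges that overlap these. Other spots with over 0.5 of the called change numbered 1 of 28 for blocker rises and 8 of 27 for bleomycin rises. At bright spots they numbered 1 of 12 and 6 of 8. For blocker falls they numbered 2 of 11 and, at bright spots, 2 of 5. Other spots thus followed the called spots less often for blocker rises than for bleomycin rises, in few genes. Over all other spots, the 0.0394 of the blocker rises met the limit fixed beforehand for a signal of single spots. The 0.198 of the bleomycin rises lay under the same limit, so meeting it does not set the blocker rises apart. Overlap of the ranges was not part of that limit. As the ranges overlap, a signal of single spots cannot be told apart from a change of the transcript by this test. An effect of the blocker in the lung and a direct effect of the oligonucleotide on some probes both stay open. The slide and date of each array were not stated, so a batch that follows the blocker in all groups was not tested.

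Some of the 29039 tested spots without a gene name also changed and were used in no comparison of the report. With the CAV1 blocker 390 changed after bleomycin (291 rose, 99 fell) and 110 after PBS (95 rose, 15 fell), and with bleomycin 87 changed under the control blocker (61 rose, 26 fell) and 16 under the CAV1 blocker (5 rose, 11 fell).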

How the results depend on the processing

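The muscle covariate alternatives and the joint omission of PBS control blocker array 2 and bleomycin CAV1 blocker array 6 (the joint omission) were chosen after seeing the data, and all other alternatives before. The cause of a change was not tested except where fewer arrays were used.

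With bleomycin under the control blocker, 489 genes became 1 with the replicate block, 0 with array weights, 215 with only the arrays compared, 115 with the fold minimum, 238 with the muscle covariate and 105 with the joint omission, and 91 to 4075 leaving out 1 array. Under the CAV1 blocker, 105 became 164 at the 50th percentile, 0 with the replicate block, 175 with the deposit-order block, 2712 with array weights, 0 with only the arrays compared, 39 with the fold minimum, 10 with the covariate, 217 with the joint omission and 160 with the covariate without bleomycin CAV1 blocker array 1, and 10 to 719 leaving out 1 array. At an unadjusted p under 0.05 limma gave 860 genes where array weights gave 0, 1729 where the block gave 0 and 3225 where only the arrays compared gave 0. Same-numbered arrays did not pair, as 3 arrays had their closest partner under their own number, so the replicate block removes degrees of freedom without a known source of variation.

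With the CAV1 blocker after bleomycin, 327 genes became 212 with the replicate block, 593 with array weights, 29 with the fold minimum and 573 in spots, and 249 to 394 leaving out 1 array. After PBS, 63 became 14 with the replicate block, 2 with array weights, 3 with only the arrays compared, 23 with the fold minimum, 157 in spots, 4 with the covariate, 220 with the joint omission and 0 (1200 at an unadjusted p under 0.05) with the covariate without bleomycin CAV1 blocker array 1, and 34 to 4024 leaving out 1 array. The interaction gave 45 with the joint omission and 0 to 3011 leaving out 1 array.

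The score difference was -0.69 with p = 0.04 when permuted within deposit order and -0.78 with p = 0.0368 with the joint omission (permutation tests), from -0.91 to -0.42 leaving out 1 array, and p was 0.125 over sign flips of same-numbered arrays. The slope was -0.059 over all genes and 0.768 to 0.994 leaving out 1 array. Lists shifted by bleomycin numbered 2 with an estimated correlation and 11 to 22 leaving out 1 array, and those shifted by the CAV1 blocker 0 with an estimated correlation, 3 with fry and 9 to 13 leaving out 1 array.

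The following values reversed. The neutrophil and the T and NK cell medians with bleomycin under the control blocker went from -0.36 to 0.039 and from -0.33 to 0.019 without PBS control blocker array 1, where the test stayed downward and lost the call. The skeletal muscle list with bleomycin under the control blocker changed by 0.051 with the covariate and 0.040 without bleomycin CAV1 blocker array 1 as well. Leaving out 1 array, Cav1 ranged from -0.68 to 0.0073 with bleomycin under the control blocker (0.0073 with the joint omission), from -0.25 to 0.44 with the CAV1 blocker after PBS and from -0.19 to 0.50 in the interaction (-0.28 with the joint omission). Dnm3 ranged from -0.32 to 0.083 and from -0.31 to 0.091 with bleomycin under the control and CAV1 blockers, from -0.087 to 0.31 and from -0.10 to 0.30 with the CAV1 blocker after bleomycin and after PBS, and from -0.19 to 0.32 in the interaction. Under the CAV1 blocker Dnm3 was 0.67 with the covariate, 0.66 without bleomycin CAV1 blocker array 1 as well and 0.091 with the joint omission, and after PBS it was -0.87, -0.91 and -0.10. Dnm3os under the CAV1 blocker was 6.73e-04 with the covariate without bleomycin CAV1 blocker array 1. Of these, Cav1 with bleomycin under the control blocker passed without PBS control blocker array 1 (-0.68, adjusted p = 0.0294), in 1 of 29 alternatives (0.0294 to 1), and the reversed values did not pass.

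Cav1 with the CAV1 blocker after bleomycin kept its direction in all 29 alternatives (0.14 to 0.30, adjusted p 0.408 to 0.876). Over 31 list results, 815 values kept direction and side of the threshold, 82 lost the call and 2 reversed, by the direction of the test. Over 157 named-gene results, 3547 kept both, 957 lost the call, 13 gained it and 23 reversed. Signal near the floor of the arrays limits genes such as Dnm3os, at 6.06 to 6.83 over the arrays.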

Other observations

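The values in this part were chosen after they were seen. PBS control blocker array 2 and bleomycin CAV1 blocker array 6 had the highest Cd79a signals, at 12.14 and 11.52, while the mean of the B cell and plasma cell list was 9.45 and 9.26 in them, within the 8.81 to 9.60 of the other arrays. The first 4 principal components held 38, 22.5, 13.5 and 5.89% of the variance.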
